A study of Xenopus tropicalis with 3 samples.

How the data were processed

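RNA was measured in animal caps of Xenopus tropicalis, the dissected prospective epidermis, at NF10.5 (gastrula), NF16 (neurula) and NF24 (tailbud). Per the labels' protocols, total RNA was depleted of ribosomal RNA with Ribo-Zero Gold and made into directional paired-end libraries. The labels give 3 biological replicates per stage. STAR 2.4.2a and RSEM 1.3.0 are named in the submitters' processing notes, without settings, and neither the labels nor the table header names a genome build.

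The deposited table holds FPKM in 35047 rows for 35028 RefSeq transcripts of 17647 genes, with 1 column per stage, per the file headers. Of the rows, 19 repeat a transcript already listed, and both rows were kept in the sum of the gene they are listed under. Every value above 0 was a multiple of 0.01 divided by 3, to within 0.01 of such a step, which is what a mean of 3 values rounded to 0.01 gives, so each value is taken as the authors' mean over the 3 replicates. The table holds no value per replicate. The depth of each library is therefore unknown, no spread between replicates could be computed, and no test between stages was possible. The limma fit planned for a table with replicate columns was replaced by the planned fallback, a fixed rule of size. No interval or detection floor can be given, since these need counts.

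The table lists transcripts, so FPKM was summed over the transcripts of each gene, a choice made after the table was seen. Gene values were compared as log2(FPKM + 1), with no further scaling between stages. The 11771 genes with at least 1 FPKM in at least 1 stage were compared. A gene is called higher or lower when its log2 difference is at least 1 in size, which is a 2-fold ratio after the addition of 1. Each of the 3 pairs of stages was compared. Genes called in opposite directions in the steps before and after NF16 are described as peaking or lowest at NF16. Both steps use the same NF16 mean, and the number that chance would give cannot be simulated without the spread of the replicates.

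Before the data were examined, 28 gene lists, a list of landmark genes, the rule of size, the rule for named genes and the first set of other settings were fixed. The planned rule for named genes also required all 3 libraries of one stage to lie above those of the other. This part cannot be applied to means and was dropped. The planned limma list test (camera) needs replicate columns, and a comparison with random lists took its place. 27 lists had at least 5 members among the genes compared, and the mitochondrial genome list had 0 members in the table. Members below 1 FPKM at all stages were left out. This left 10 of 28 measured keratin and vimentin genes, 19 of 28 goblet and mucin, 22 of 29 ionocyte and 12 of 16 small secretory genes. A member below 1 FPKM at NF10.5 is compared only if it reaches 1 FPKM later, so counts of higher members are partly built in. For each list, the percentile of its median log2 difference was taken among the medians of 10000 random lists of the same size, matched on mean expression in 20 bins. A list at or below percentile 2.5 or at or above percentile 97.5 is said to stand apart, as a description of these libraries and not as a test between stages. Named genes are, per comparison, the 6 genes with a symbol and the largest log2 difference in each direction among those with at least 10 FPKM in the higher stage, all measured landmark genes, and up to 4 members per list with the largest called differences. Where a list had no called member, those with the highest mean FPKM are named. For genes peaking or lowest at NF16, the 5 whose smaller step was largest are named. Symbols come from the table, or, for list members listed under a locus identifier, from a RefSeq gene table of assembly UCB_Xtro_10.0, which matched 15711 of 17647 genes (89.0%) and was used only for names and neighbours.

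Isoforms were compared by the share of each transcript in its gene's summed FPKM, by a rule chosen after the table was seen. A switch is a gene with at least 10 FPKM at both stages whose leading transcript differs, where the later leader gains and the earlier leader loses at least 30 percentage points. The authors' assignment of reads to overlapping transcripts cannot be checked from FPKM.

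The steps were tested on simulated data for NF16 against NF10.5, with 10131 genes passing the filter and a noise SD of 0.25 on the log2 scale, an assumed value. Of 50 genes planted at a log2 change of 2, 50 were called, and 50 of 50 at -2. At a log2 change of 1.5, 45 of 50 were called, and 45 of 50 at -1.5. Of 9931 unchanged genes, 31 (0.312%) were called. A planted list of 30 genes at 2-fold lay at percentile 100, and 3 of 100 unchanged lists stood apart. The unchanged lists were random draws with independent noise, scored against other random draws. A small share standing apart was therefore fixed in advance and checks only the computation. It does not tell how often real lists, whose members may vary together, would stand apart. Changes were planted, and lists drawn, only among genes with at least 5 FPKM at NF10.5. These shares therefore do not cover genes of lower FPKM, where the addition of 1 makes the log2 difference smaller.

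The settings fixed in advance for comparison were a pseudocount of 0.1 or 5, no low-value filter, a filter at 5 FPKM, scaling of each stage to a common total (TPM), median-of-ratios scaling, and quantile normalization. Settings added after seeing the data were the highest transcript in place of the sum, each transcript by itself, and isoform rules with 5 or 20 FPKM or 20 or 40 points. No paired analysis was possible because the table has no replicate columns. Computation used Python 3.11.15 with numpy 2.4.6 and pandas 2.3.3, and figures were drawn with matplotlib 3.10.9. All 3 columns of the table were used.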

Results

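The transcriptome of the animal cap, the ectoderm that forms the mucociliary epidermis of the Xenopus tadpole, was measured at the gastrula (NF10.5), neurula (NF16) and tailbud (NF24) stages. The design asks which genes and which splice isoforms differ between these stages. Each stage is represented by the authors' mean FPKM over 3 labelled biological replicates, so no error can be given for any value and none of the differences has a replicate check. The table gives no sequencing depth. FPKM summed to 578836 at NF10.5, 531531 at NF16 and 505996 at NF24, and 9993, 10556 and 10785 genes reached 1 FPKM in that order. The most abundant gene was the unnamed LOC101731852 at NF10.5, with 1.60% of the total, and the keratin krt5.7 at the later stages, with 3.21% at NF16 and 4.46% at NF24.

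Between gastrula and neurula, motile axoneme, ionocyte, secretory and keratin genes were mostly higher at NF16, while pluripotency, oocyte and cell cycle genes were mostly lower. The gene with the largest increase among those with a symbol was itln1, a secreted lectin of the epidermal mucus, with 1.58 FPKM at NF10.5 and 547 FPKM at NF16, a log2 difference of 7.73. It was followed by the cilium gene odf3 (1.18 and 416 FPKM), the otogelin gene otog (0.623 and 304 FPKM), itln2 (0.967 and 336 FPKM), fcgbp (0.643 and 277 FPKM) and crocc2 (0.68 and 282 FPKM). The largest decreases among genes with a symbol were in the mitotic cyclin ccnb1 (296 and 3.03 FPKM, log2 -6.21), hpdl (237 and 3.2 FPKM), gs17 (219 and 3.08 FPKM), the Nodal co-receptor gene tdgf1.3 (335 and 5.60 FPKM), pou5f3.3 and pou5f3.2.

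Of 114 motile axoneme genes, 106 were higher at NF16 and 0 were lower, with a median log2 difference of 3.57 against -0.74 for matched random lists (percentile 100). The tubulin tuba1a went from 14.4 to 2287 FPKM, the tektins tekt1 and tekt2 from 0.233 to 122 and from 1.31 to 173 FPKM, efhc2 from 0.34 to 146 FPKM and the central pair gene spag6 from 0.97 to 192 FPKM. The outer arm dynein dnah9 differed by a log2 of 2.97. Among 54 genes of the intraflagellar transport and BBS list, which also holds other cilium genes such as nphp4, mks1 and cep290, 25 were higher and 5 lower (median 0.93 against -0.80, percentile 100), and 39 and 3 under median-of-ratios scaling. Here wdr19 had 1.77 and 19.99 FPKM and ttc26 had 8.30 and 56.6 FPKM, while bbs10 dropped from 31.5 to 2.06 FPKM and nphp4 from 13.0 to 1.34 FPKM.

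Regulators of multiciliated cells went both ways, with 14 of 31 higher and 8 lower (median 0.91 against -0.77, percentile 99.99). The deuterosome gene ccdc67 (deup1) had 0.0867 FPKM at NF10.5 and 26.2 at NF16, cdc20b 0.34 and 44.5, foxn4 1.12 and 56.4, and the coactivator gene mcidas 1.23 and 50.9. In contrast gmnc, which acts at the top of this cascade, was at 18.7 FPKM at NF10.5 and 0.823 at NF16. The ciliogenesis factor foxj1 was already at 47.9 FPKM at NF10.5 and had 98.9 at NF16, and myb had 7.88 and 17.3, a log2 difference of 1.04 that was 0.18 for its highest transcript. The value for rfx2 was 97.51 FPKM at NF10.5 and 109.6 at NF16.

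Ionocyte genes showed 17 of 22 higher and 4 lower (median 2.95 against -0.60, percentile 100). The anion exchanger slc26a4 had 0.463 and 244 FPKM, carbonic anhydrase ca2 0.277 and 120.3, and the proton pump subunits atp6v1b1 and atp6v1g3 0.337 and 107, and 1.44 and 186. Transcription factor genes of this list went both ways. The log2 differences were 5.37 for ubp1, 4.06 for dmrt2 and 1.77 for foxi1, while foxi2 was lower, with 170 and 9.85 FPKM (log2 -3.98). Both foxi1 and foxi2 are also in the list of early ectoderm regulators. The gene ca12 differed by 1.06. Of 18 V-ATPase genes compared, 7 were higher and 3 lower (median 0.51 against -0.44, percentile 98.36), and 10 and 1 under median-of-ratios scaling. The called subunits included atp6v1c2 and atp6v0a4, with 75.5 and 63.5 FPKM at NF16. This list shares atp6v1b1, atp6v1c2, atp6v1g3, atp6v0d2 and atp6v0a4 with the ionocyte list, so it is not separate evidence.

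Small secretory cell genes were higher in 9 of 12 cases and lower in 0 (median 2.43 against -0.38, percentile 100). The monoamine transporters slc18a1 and slc18a2 stood at 0.45 and 0.273 FPKM at NF10.5 and at 211 and 93.2 FPKM at NF16, chga at 2.19 and 134 FPKM, and the regulator foxa1 at 1.12 and 64.6 FPKM. The landmark otogl stayed below 0.03 FPKM at all stages, whereas otog was abundant. Goblet and mucin genes had 15 of 19 members higher and 0 lower (median 2.31 against -0.26, percentile 100), among them itln1, itln2, fcgbp and agr2, the last with 9.27 and 672 FPKM. The secretory regulators spdef (2.48 and 3.12 FPKM) and xbp1 (227 and 143 FPKM) were not called, and the landmark hspb1 was listed at 0 at all stages.

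Structural genes followed, with 7 of 10 keratin and vimentin genes higher (median 2.19 against -0.07, percentile 99.97). At NF16 krt5.7 reached 17079 FPKM, krt 12721, krt8 3627 and krt19 328, from 690.5, 611, 397 and 1.63 FPKM. Junction and basement membrane genes were higher in 21 of 41 cases and lower in 5 (median 1.29 against -0.30, percentile 100), including the plakins ppl (log2 5.65) and evpl (5.05), cldn34 (5.27) and a claudin listed as LOC100485738 (5.51). E-cadherin, cdh1, had 31.7 FPKM at NF10.5 and 497 at NF16, while LOC100485633, now named cdh3, had 471 and 225, a log2 difference of -1.06 that was -0.94 with TPM and -0.25 under median-of-ratios scaling. Early ectoderm regulators were higher in 17 of 27 cases and lower in 4 (median 1.53 against -0.42, percentile 100), with tp63 at 7.51 and 212 FPKM, gata3 at 1.88 and 55.3 and dlx3 at 54.1 and 609. The lower members included foxi2 (log2 -3.98) and foxi4.2 (-2.95). Neither tfap2a (log2 0.72) nor grhl3 (0.30) was called as deposited, though both passed the rule under median-of-ratios scaling, at 1.52 and 1.105. Ribosomal protein genes were higher in 63 of 69 cases and lower in 0 (median 1.58 against 0.26, percentile 100), for example rps2 with 41.7 and 403 FPKM and rpl26 with 67.9 and 409 FPKM.

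Pluripotency and ventral genes were lower in 19 of 24 cases and higher in 0 (median -1.82 against -0.42, percentile 0.02). The Oct4-type factors pou5f3.1, pou5f3.2 and pou5f3.3 had 136, 288 and 110 FPKM at NF10.5 and 30.02, 6.26 and 1.47 FPKM at NF16, sox3 had 793 and 89.3, ventx1.2 97.8 and 14.6, and ventx2.1 348 and 127, the last a log2 difference of -1.45 that was -0.64 under median-of-ratios scaling. Oocyte and maternal genes were lower in 20 of 25 cases (median -2.39 against -0.67, percentile 0), including the linker histone h1foo (log2 -5.06), zar1l (-4.44), cpeb1 (-4.24), vegt (-3.06) and gdf1 (-2.43). Cell cycle genes were lower in 57 of 70 cases and higher in 0 (median -1.998 against -0.62, percentile 0), with birc5.1 at 164 and 4.72 FPKM, cenpa at 161 and 5.44 and ccnb2 at 919 and 48.3. Median-of-ratios scaling gave 40 lower and 1 higher here, 15 and 1 for oocyte genes, and 13 and 2 for pluripotency genes. Histone genes were lower in 13 of 24 cases and higher in 4 (median -1.39 against -0.11, percentile 0.03), with hist1h2aa and hist1h2am each lower and the variants h2afy and h1f0 each higher. Under median-of-ratios scaling 9 histone genes were lower and 5 higher. Near-identical histone copies share reads, so the values of single histone genes are uncertain. On the fixed list of ribosome biogenesis genes, 35 of 58 were lower (median -1.18 against -0.67, percentile 0.95), with 15 lower and 5 higher under median-of-ratios scaling and 22 and 3 under quantile normalization. Lower members included utp11l, wdr75 and ddx56, and nsun2 (132 and 10.2 FPKM) led by size, its place on the list resting on the list alone.

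Markers of other cell types moved with stage as well. Mesoderm and muscle markers were higher in 15 of 29 cases and lower in 3 (median 1.13 against -0.42, percentile 100), with nkx2-5 at 0.0867 and 96.5 FPKM, mylpf at 0.113 and 39.6, actc1 at 0.647 and 50.2 and myl1 at 1.37 and 36.7. Cement gland markers were higher in 4 of 5 cases (percentile 98.99), including agr2, pitx1 and ag1. Their list shares agr2 and muc2 with the goblet and mucin list. Neural crest markers were higher in 7 of 12 cases (percentile 99.41), with snai2, c3 and msx1 higher and the pigment gene dct lower. That list shares msx1 and tfap2e with the ectoderm regulators and foxd3 with the pluripotency genes. Endoderm markers were lower in 8 of 13 cases (median -1.86 against -0.30, percentile 0.1), including mix1, sox17b.2 and foxa4, but the apolipoprotein gene listed as LOC100489130 (apoc1) had 11.96 and 134 FPKM. The neural list had 6 members higher and 6 lower of 24 (percentile 93.95), with rax and hoxb9 higher and sox2 lower, and the 5 myeloid genes (percentile 43.83) included ptprc, lower. Stress response genes were higher in 9 of 22 cases and lower in 3 (median 0.89 against -0.50, percentile 99.66), and 17 and 2 under median-of-ratios scaling. Their list holds heat shock and immediate-early genes and others such as atf4, cdkn1a and hmox1. Among them jun stood at 3.43 and 76.7 FPKM and hsp70 at 0.25 and 18.1, with hspa1b higher and gadd45b lower. Whether handling accounts for these differences was not tested.

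Of 34 Wnt and BMP pathway genes, 11 were higher and 10 lower as deposited, 22 and 5 under median-of-ratios scaling and 16 and 6 under quantile normalization (median 0.65 against -0.50, percentile 99.86), with tbx3 (log2 5.50) and fzd6 (3.36) higher and sp5l (-3.80) and prickle1 (-3.33) lower. Notch pathway genes had 5 higher and 5 lower of 28 (percentile 91.61), notch2, hes3.3 and dll4 higher and hes7.1 lower. The 54 splicing regulators had 8 higher and 11 lower (percentile 38.0), with mbnl2 and ptbp3 higher, elavl2 and srsf7 lower, and the epithelial splicing factor esrp1 at 65.4 and 333 FPKM. Nuclear respiratory chain genes had 3 higher and 9 lower of 68 (percentile 91.38), atp5j2 higher and ndufaf5, ndufaf3 and sdha lower. The medians of the Notch, splicing, respiratory chain and myeloid lists were -0.09, -0.18, -0.10 and -0.17 and turned positive under median-of-ratios scaling, at 0.65, 0.56, 0.70 and 0.36. Because that scaling raises all genes at NF16 relative to NF10.5, this change of sign is not particular to these lists. That scaling gave 26 respiratory chain genes higher and 2 lower, 19 splicing regulators higher and 3 lower, and 9 Notch genes higher and 2 lower, and sdha was then not called, at -0.97. Quantile normalization gave 16 respiratory chain genes higher and 7 lower.

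In all, 2466 of 11771 genes were higher and 4586 lower at NF16, and the median over all compared genes was -0.57. This split depends on scaling: median-of-ratios scaling shifted the median by 0.68 and gave 3558 higher and 2418 lower, quantile normalization 2689 and 3538, and TPM 2829 and 4457, so the list medians above are read against matched lists. With no low-value filter, the V-ATPase and neural crest lists no longer stood apart, at percentiles 96.86 and 97.18, and with a pseudocount of 5 ca12, dll4, foxj1, gdf1, hspa1b and myb were not called.

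**Figure D1:**
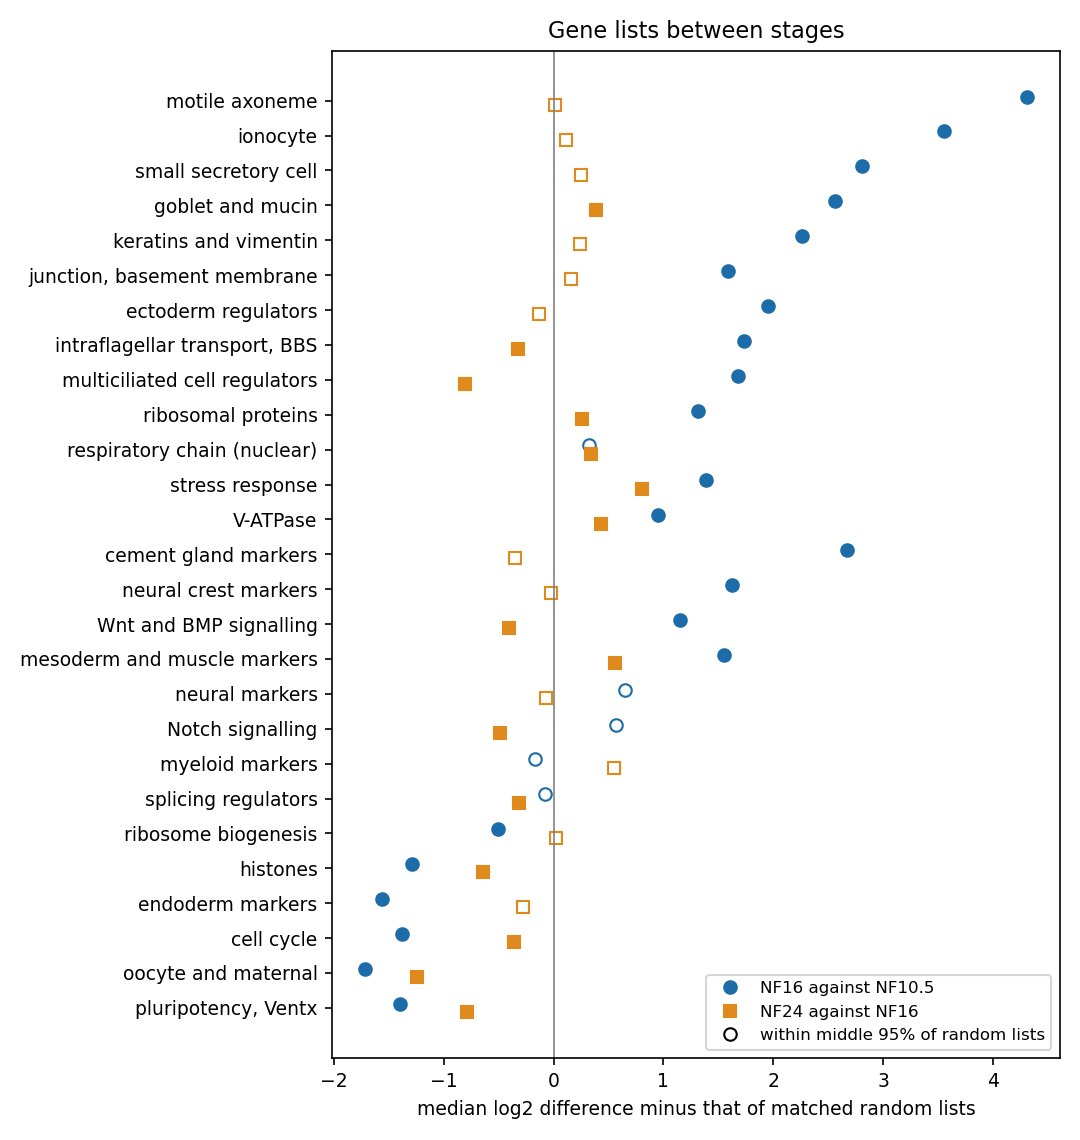
Median log2 difference of each gene list minus that of its expression-matched random lists (x axis) for NF16 against NF10.5 (circles) and NF24 against NF16 (squares), where open symbols lie within the middle 95% of random lists. The motile axoneme list lies at 4.31 in the first step and 0.02 in the second, and no error bars are drawn because each stage has a single deposited mean.

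From neurula to tailbud far fewer genes differed, and the list of multiciliated cell regulators was lower while most motile axoneme genes were not called. Among genes with a symbol, the largest increases were in thioredoxin, txn (3.54 FPKM at NF16 and 58.5 at NF24, log2 3.71), the glutathione transferase gstp1 (13.0 and 175), the serine protease gene prss29 (43.0 and 547), the collagenase gene mmp1 (1.46 and 29.0), crisp2 (5.103 and 71.7) and fgfbp1 (1.22 and 22.4). In the same set, decreases were largest in mcidas (50.9 and 2.78 FPKM, log2 -3.78), cdc20b (44.5 and 2.96), znf329 (30.2 and 2.02), the meiotic regulator fbxo43 (20.2 and 1.11), the centriole gene poc1a (38.5 and 2.97) and ccna1 (125 and 12.5).

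Multiciliated cell regulators were lower in 11 of 31 cases and higher in 0 (median -0.65 against 0.16, percentile 0), with ccno (50.3 and 5.45 FPKM) and ccdc67 (26.2 and 2.58) beside mcidas and cdc20b. The value of foxj1 was 58.9 FPKM at NF24, that of myb 10.02 and that of rfx2 48.0, the last a log2 difference of -1.17. Motile axoneme genes instead stayed near their NF16 values, with 111 of 114 not called (median 0.14 against 0.12, percentile 61.48), tekt3 and pifo higher and dnaaf2 lower, the last not called with TPM, at -0.999. Intraflagellar transport and BBS genes had 53 of 54 not called, and bbs12 was lower, while the list as a whole lay below matched lists (median -0.17 against 0.15, percentile 0.02).

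Goblet and mucin genes were higher in 6 of 19 cases and lower in 0 (median 0.39 against 0.01, percentile 99.46). The list no longer stood apart with a pseudocount of 5, a filter at 5 FPKM or no filter, at 0.17, 0.23 and -0.0047 relative to matched lists. Its called members included itln2 at 336 and 954 FPKM, spdef at 3.12 and 9.91, galnt12 at 10.8 and 28.1 and tmprss2 at 1.58 and 8.82, and spdef was not called for its highest transcript (0.86). Here itln1 reached 1118 FPKM, a log2 difference of 1.03 that was 0.90 under median-of-ratios scaling. Small secretory genes had 3 of 12 higher (percentile 89.76), namely ddc (14.8 FPKM at NF24) and the less abundant scg3 and pcsk1, the last not called under quantile normalization (0.78). Ionocyte genes had 20 of 22 not called (percentile 79.7), with bsnd higher and ubp1 at 85.7 and 41.2 FPKM. The log2 difference of ubp1 was -1.04 as deposited and between -0.97 and -0.99, and so not called, with TPM, quantile normalization, a pseudocount of 5 or its highest transcript. V-ATPase genes had 0 of 18 called but a median of 0.42 against -0.01 (percentile 99.94), the most abundant being atp6v0c (195 and 265 FPKM).

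Keratins had 1 of 10 higher (percentile 90.44), a keratin gene of low value listed as LOC100490729, and junction genes 2 of 41, among them col17a1 (percentile 95.27). Ectoderm regulators went both ways, with 3 higher and 4 lower of 27 (percentile 13.73), where dlx4 (log2 1.77) and elf3 were higher and klf5 (-1.82) and bmp7.2 lower, and tp63 went from 212 to 106 FPKM. Keratin krt5.7 stood at 22588 FPKM at NF24, krt at 7363 and cdh1 at 619.9. Ribosomal protein genes had 0 of 69 called (median 0.03 against -0.23, percentile 99.97), rpl37 and rps25 among the most abundant, and their median was -0.10 under median-of-ratios scaling. Nuclear respiratory chain genes had 3 of 68 higher, and 8 with TPM (median 0.34, percentile 100), those as deposited being ndufaf4, ndufs6 and ndufb2. Ribosome biogenesis genes, with npm1 the most abundant, had 0 of 58 called (percentile 61.79).

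Earlier programs were lower again: 9 of 24 pluripotency and ventral genes (median -0.74 against 0.05, percentile 0), led by pou5f3.1 (30.02 and 3.45 FPKM), with mycn higher except under median-of-ratios and quantile scaling, and 13 of 25 oocyte genes (median -1.08 against 0.17, percentile 0), including zp2 and zpax. Cell cycle genes were lower in 10 of 70 cases (median -0.28 against 0.08, percentile 0), among them ccne1 and mcm3, and histones in 8 of 24 cases, and in 5 under quantile normalization (median -0.73 against -0.09, percentile 0.01), among them h1fx. Notch genes were lower in 8 of 28 cases (percentile 0.02), including hes3.3, hes3.1, hes5.1 and LOC733709 (now hes5.9). Splicing regulators were lower in 6 of 54 cases, and in 12 under median-of-ratios scaling (median -0.39 against -0.08, percentile 0.1), with ptbp1 at 606 and 206 FPKM, hnrnpk at 1099 and 390.1, hnrnpab at 1466 and 539 and hnrnpa0 at 162 and 55.5. Wnt and BMP genes lay below matched lists (percentile 0.02), though 28 of 34 were not called. Of the others 4 were lower, including sp5l, wnt8a and celsr2, and 2 higher, including nog.

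Stress response genes were higher in 9 of 22 cases and lower in 1, and higher in 7 under median-of-ratios scaling (median 0.86 against 0.05, percentile 100), with hsp90aa1.1 at 13.5 and 101 FPKM, hspa5 at 107 and 348, fosl1 at 2.51 and 15.5 and egr1 at 2.66 and 11.9. Mesoderm and muscle markers were higher in 7 of 29 cases and lower in 3, and higher in 11 with TPM (median 0.72 against 0.16, percentile 100), including tnnc2 (3.62 and 14.4 FPKM) and tal1, with the mesoderm gene t lower. Neural genes had 3 of 24 higher (percentile 30.97), stmn2, tubb3 and tubb2b. Neural crest genes had sox9 higher and dct and ets1 lower (percentile 45.8), myeloid genes spib and cebpa higher (percentile 91.39), and cement gland (percentile 15.43) and endoderm genes (percentile 6.61) had 0 called members as deposited. Under TPM, median-of-ratios and quantile scaling alike, 2 endoderm genes were lower, among them foxa4 (-1.10, -1.02 and -1.03).

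A total of 813 genes were higher and 570 lower at NF24 than at NF16, with a median of 0.12 over all genes. Under median-of-ratios scaling the median became 0.01, with 653 genes higher and 773 lower, and quantile normalization gave 659 and 800. With TPM 1227 genes were higher and 626 lower. Both counts rose with TPM, which a change of scale between stages would not do by itself. TPM also lowers the weight of the pseudocount, and these effects were not separated. The TPM counts given for gene lists and for the other comparisons carry the same limit. The counts ranged from 271 higher and 270 lower with a pseudocount of 5 to 1343 and 980 with 0.1, and with no low-value filter the mesoderm and muscle list (0.048 relative to matched lists) no longer stood apart. With a pseudocount of 5, which weighs against genes of low FPKM, calls that ended included bsnd, cebpa, col17a1, dct, dnaaf2, elf3, hes5.1, LOC100490729, mcm3, ndufs6, nog, pcsk1, pifo, scg3, sox9, spdef, spib, stmn2, tal1, tubb2b, ubp1 and wnt8a.

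Over the whole interval from gastrula to tailbud, motile axoneme, ionocyte, secretory and keratin genes were mostly higher and oocyte, pluripotency and cell cycle genes mostly lower. The largest increase among genes with a symbol was in itln2, which at NF24 had 954 FPKM against 0.967 at NF10.5 (log2 8.92). It was followed by itln1 (1118 against 1.58 FPKM, log2 8.76), msln (1448 against 3.83 FPKM, log2 8.23), fcgbp, otog and odf3. Decreases, again among genes with a symbol, were largest in hist1h2am (270.0 FPKM at NF10.5 and 0.35 at NF24, log2 -7.65), tdgf1.3 (-7.36), ccnb1 (-7.21), pou5f3.2 (-7.01), mkrn3 (705 and 4.82 FPKM) and gs17 (-6.75).

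Of the 27 lists, 14 stood above and 6 below matched random lists. Motile axoneme genes were again higher in 106 of 114 cases (median 3.77), with tekt1, efhc2 and spag6 among them, and all 25 oocyte genes compared were lower as deposited. Multiciliated cell regulators, which had stood apart upward at NF16, did not at NF24 (7 higher and 11 lower of 31, percentile 68.23), with gmnc at 0.163 FPKM, mcidas at 2.78, fank1 and znf474 still higher and e2f1 lower. Their median of -0.40 became 0.17 under median-of-ratios scaling, with 9 higher and 6 lower. Stress response genes were higher in 13 of 22 cases and lower in 2 (median 1.77 against -0.46, percentile 100), and mesoderm and muscle markers were higher in 20 of 29 cases and lower in 5 (median 1.36 against -0.20, percentile 99.99). At NF24, 17 of 22 ionocyte genes were higher than at NF10.5 and 3 lower, 16 of 19 goblet genes higher and 2 lower, and 11 of 12 small secretory and 8 of 10 keratin and vimentin genes higher with 0 lower, and 56 of 70 cell cycle genes were lower. Outside the skeletal muscle genes described below, 82.0% of the 1758 compared genes below 1 FPKM at NF10.5 were higher at NF24. The filter thus accounts for part of such counts where members were below 1 FPKM at NF10.5. Under median-of-ratios scaling 44 cell cycle genes were lower and 2 higher. The dissimilarity of the gastrula was visible across genes, where Pearson's r of log2 values was 0.63 for NF16 with NF10.5, 0.53 for NF24 with NF10.5 and 0.95 for NF24 with NF16, genes not being independent replicates.

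Altogether 2984 genes were higher and 4342 lower, with a median of -0.44, against 3937 and 2730 under median-of-ratios scaling, which shifted the median by 0.60, 3417 and 4070 with TPM and 2987 and 3774 under quantile normalization. The nuclear respiratory chain (percentile 97.66), neural crest and endoderm lists no longer stood apart with no low-value filter, at 97.44, 94.25 and 2.56, and a pseudocount of 5 also ended the respiratory chain call, at 97.4.

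**Figure D2:**
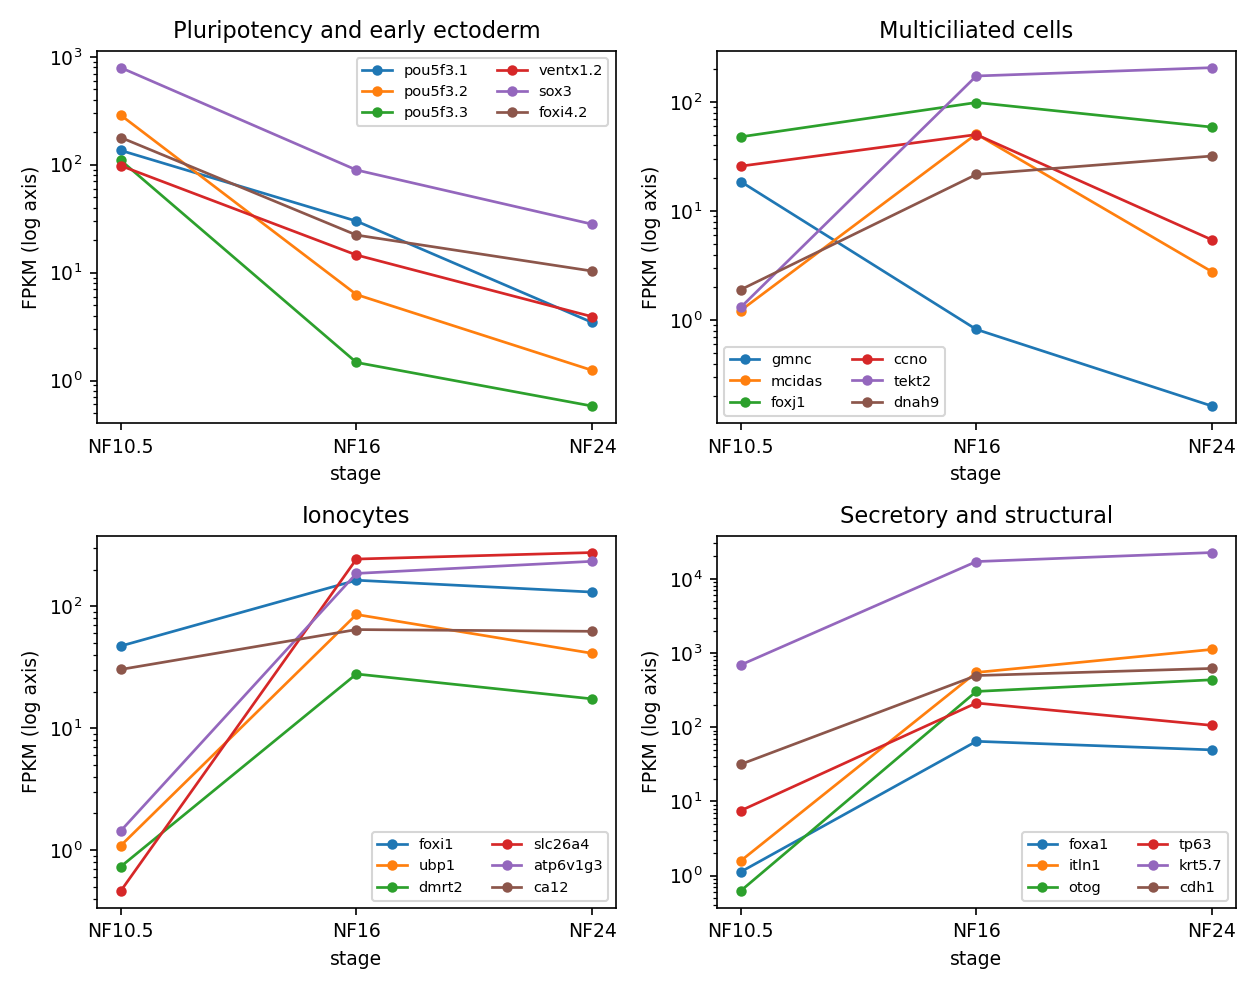
FPKM on a log axis at the 3 stages for genes of pluripotency and early ectoderm, multiciliated cells, ionocytes, and secretory and structural programs, each point being the authors' mean over 3 replicates, with no error available. In the multiciliated panel gmnc is highest at NF10.5 (18.7 FPKM), mcidas at NF16 (50.9 FPKM) and tekt2 at NF24 (206 FPKM).

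Genes that peaked at the neurula stage were led by regulators of multiciliated cells. The 5 with the largest smaller step were mcidas, cdc20b, znf329, poc1a and the UDP-glucose dehydrogenase gene ugdh.2, which had 48.5, 422 and 48.2 FPKM at NF10.5, NF16 and NF24. Of 31 multiciliated cell regulators, 8 (25.8%) peaked at NF16, against 1.16% of all genes compared: ccdc67, cdc20b, cenpj, cep152, foxn4, mcidas, plk4 and stil, most of which act in centriole assembly. Other list members that peaked included gata2, klf5, hes3.3, hes5.1, h1f0, ptbp1 and, only as far as its second step is called, ubp1. Genes lowest at NF16 were led by the protease gene adamts1 (28.8, 5.07 and 25.5 FPKM), the chloride channel gene ano1 (19.8, 4.81 and 32.7), adcy4, endog and atp13a4. In all, 136 genes peaked and 150 were lowest at NF16, and median-of-ratios scaling gave 248 and 42, and a pseudocount of 5 gave 69 and 22. A larger group of 2057 genes was higher at NF16 and not called afterwards, 273 were higher in both steps, and 279 were lower in both.

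The series also set out to describe splice isoforms, and large changes of the leading transcript were mostly between gastrula and neurula. The leading transcript differed in 351 of 2272 genes between NF10.5 and NF16 and in 199 of 2711 between NF16 and NF24, before any limit on the size of the change. In rab27b, a small GTPase of secretory vesicle traffic, NM_001005681.2 held 1.03% of the gene's FPKM at NF10.5 and 96.0% at NF16, in place of NM_001195546.1. The share of the later leading transcript went from 0 to 85.9% in efcab7, from 3.35 to 89.1% in the adaptor gene ap3b1, from 2.95 to 87.8% in larp6, from 11.4 to 91.7% in the desmosomal gene perp and from 0.528 to 80.4% in pcnxl4. Members of the fixed lists that switched included the axoneme gene tctex1d1 (31.8 to 92.3%), the centriole gene sass6 (26.6 to 77.6%), the junction gene itga6 (33.1 to 73.3%), and also rps10, incenp, prickle1, galnt7 and ets1. These genes, named by the size of the switch or by their list, were chosen after their values were seen.

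By this rule 118 of 2272 genes (5.19%) switched between NF10.5 and NF16, and 54 of these were not called at the gene level. Between NF16 and NF24, 8 of 2711 genes (0.295%) did, among them aim1, cdkal1, tpp2, tbc1d16, tsc22d1 and atp12a. In aim1, XM_004914553.3 went from 22.5 to 72.4%, and in the proton pump gene atp12a, NM_001005025.1 went from 34.3 to 64.8%. From NF10.5 to NF24, 157 of 2368 genes switched, and 96 genes switched in both comparisons with NF10.5, 94 of them to the same transcript. The numbers follow the limits chosen: with a gain of 40 points 70, 2 and 97 genes switched in the 3 comparisons, and with 20 FPKM per gene 66, 4 and 90 did.

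**Figure D3:**
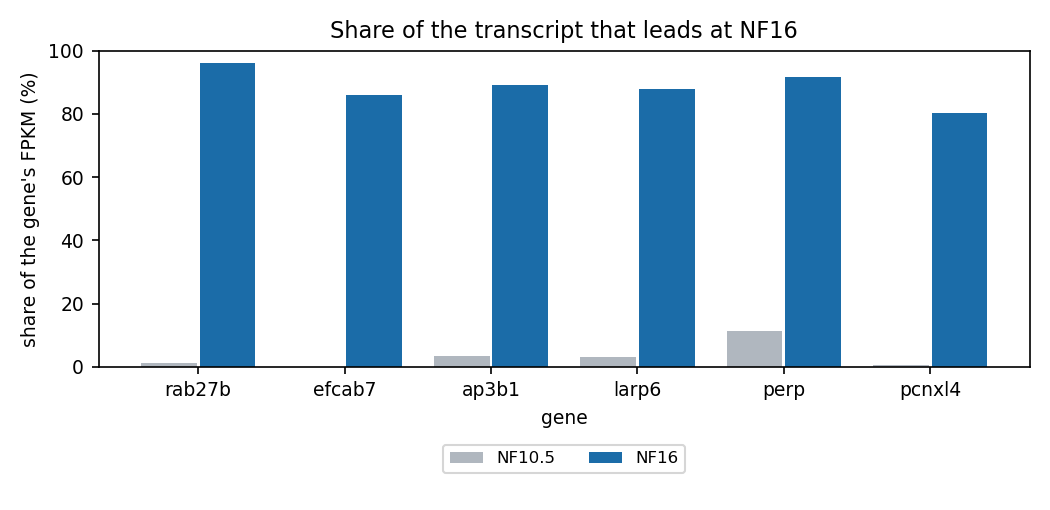
Share of each gene's summed FPKM (percent) held by the transcript that leads at NF16, at NF10.5 (grey bars) and NF16 (blue bars), for the 6 genes with the largest gain. In rab27b the share is 1.03% at NF10.5 and 96.0% at NF16, and no error bars are drawn because each value is a ratio of deposited means.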

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

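The isoform limits, the highest transcript and each transcript by itself were tried after seeing the data. Over all settings fixed in advance and the highest transcript, 3011 values of named genes kept their side of the rule of size and 79 did not, 45 of them with a pseudocount of 5. The filter settings cannot change a gene's log2 difference. Of the 3011, 388 with no filter and 375 with a filter at 5 FPKM were therefore fixed in advance. For gene lists, 544 values kept their place against matched lists, 19 changed it and 1 reversed. Among gene counts, no filter, a filter at 5 FPKM and the highest transcript left all within 1.5 times. With no filter this was fixed in advance, because a gene below 1 FPKM at all stages cannot be called. For NF16 against NF10.5, median-of-ratios scaling gave 2418 lower, and transcripts by themselves 4107 higher and 7304 lower. For NF24 against NF16, a pseudocount of 0.1 gave 1343 higher and 980 lower, a pseudocount of 5 gave 271 and 270, TPM 1227 higher, and transcripts 1480 and 1172. For NF24 against NF10.5, a pseudocount of 5 gave 1974 higher, median-of-ratios scaling 2730 lower, and transcripts 4927 and 7119. Genes peaking at NF16 numbered 69 with a pseudocount of 5, 248 with median-of-ratios scaling and 362 as transcripts. Genes lowest at NF16 numbered 347 and 22 with pseudocounts of 0.1 and 5, 251 with TPM, 42 with median-of-ratios scaling, 82 with quantile normalization and 307 as transcripts. Transcript counts are larger because more units are counted, and isoform counts follow their limits. A smaller pseudocount widens the log2 differences of genes of low FPKM and a larger one narrows them. Median-of-ratios scaling moves all genes of a stage by 1 factor. TPM mixes a factor per stage with a lower weight of the addition of 1, and these were not separated. For quantile normalization the cause was not tested. Isoform switches from NF10.5 to NF16 numbered 66 at 20 FPKM, 179 at 20 points and 70 at 40 points. From NF16 to NF24 they numbered 20 at 5 FPKM, 4 at 20 FPKM, 31 at 20 points and 2 at 40 points, and from NF10.5 to NF24 90 at 20 FPKM and 97 at 40 points. List medians relative to matched lists changed their call as follows, and the cause was not tested. With no low-value filter the values were -0.0047 for goblet and mucin genes and 0.048 for mesoderm and muscle markers, which lost their call, and 0.27 for small secretory genes, which gained it, all NF24 against NF16. Calls were also lost there for neural crest markers at 0.54 (NF16 against NF10.5) and 0.52 (NF24 against NF10.5), V-ATPase genes at 0.73 (NF16 against NF10.5), and endoderm markers at -0.37 and respiratory chain genes at 0.49 (NF24 against NF10.5), while cement gland markers gained one at 1.93. That list also gained one at 3.31 with a pseudocount of 0.1 and at 2.75 with TPM (NF24 against NF10.5). For NF24 against NF16, endoderm markers gained a call at -0.72 with a pseudocount of 0.1, motile axoneme genes at 0.11 with quantile normalization, and goblet genes lost theirs at 0.17 with a pseudocount of 5 and at 0.23 with a filter at 5 FPKM. For NF24 against NF10.5, a pseudocount of 5 ended the respiratory chain call at 0.45 and gave a call for splicing regulators at -0.48. Quantile normalization did so too for splicing regulators, at -0.56, and for Wnt and BMP genes at 0.82, as did median-of-ratios scaling for the latter at 0.79. Not run, because the table has no replicate columns, were the choice of samples in the fit, other variance models, a threshold on adjusted p alone, the replicate block, leaving out each replicate, the estimated correlation between genes and a self-contained list test. Depth is unknown, so it cannot be said which low values it limits.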

Other observations

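Several of the genes with large increases at NF16 carry only a locus identifier and were chosen for mention after their values were seen. LOC100493464 had 8.94 FPKM at NF10.5, 4468 at NF16 and 5563 at NF24, LOC100492585 had 7.83, 3375 and 4294, and LOC733521 had 4.75, 2198 and 4118. LOC101733219 instead had 5.08, 3021 and 1219. LOC100145611, now named slc26a4l, had 0.653, 335 and 496 FPKM, and LOC100490289, now named tuba1cl.1, had 5.36, 1107 and 739.8.

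Some genes listed by locus identifier were also higher at NF24 than at NF16, and these too were chosen after their values were seen. LOC100490918 (phyhdlb) had 17.7 FPKM at NF16 and 212 at NF24, LOC101734170 (phyhdla.1) 9.79 and 98.2, LOC100490748 (phyhdla.2) 40.4 and 246, and LOC100490235 (phyhdla.3) 63.8 and 361. For nemf, XM_012969248.2 had 704, 3898 and 3711 FPKM at the 3 stages while XM_002938127.4 had 45.1, 4.51 and 8.31.

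Among the tests that follow, those on muscle and on histone clusters were chosen after the values were seen. The median log2 difference of all compared genes was -0.57 at NF16 against NF10.5. With the stage totals set equal over all genes (TPM) it was -0.50, and without the 50 most abundant genes it was still -0.37. Only the step from -0.50 to -0.37 can reflect a larger share for these genes. That share may therefore account for part of the shift and not for all of it. Over the 6811 genes with a mean of at least 10 FPKM it was -0.68, which argues against low values as the cause. What stays open is a difference between stages in RNA content, or in composition beyond the 50 most abundant genes, neither of which was tested. The choice of scaling also stays open. The median ran up to 0.12 under median-of-ratios scaling, which is built to bring it near 0 and so cannot decide the question.

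Skeletal muscle transcripts were higher at NF24, for which a candidate explanation is muscle cells carried along with the dissected tissue. Of 24 muscle genes compared, from 42 listed, 22 (91.7%) were higher at NF24 than at NF10.5, the other members being pygm (62.6 and 53.9 FPKM) and jph1 (11.2 and 3.34 FPKM). This share decides nothing, because 4 of the 24 reached 1 FPKM at NF10.5 and 82.0% of the 1758 other compared genes below 1 FPKM at NF10.5 were also higher at NF24. The most abundant at NF24 were actc1 (93.2 FPKM), myl1 (69.3) and mylpf (65.1), the 24 genes made up 0.0928% of all FPKM, 7 are also in the mesoderm and muscle list, and the labels name no sort that would remove muscle cells. Carried-along muscle and low expression by the cap cells themselves cannot be told apart for these genes.

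The most abundant genes with only a locus identifier at NF10.5 may be members of histone clusters. Of the 50 such genes with the highest FPKM, 44 could be placed in the reference gene table, and 16 of these (36.4%) lay within 20 kb of a gene with a histone symbol, against 56 of 1104 (5.07%) of the other locus genes compared, 55 of them near a histone gene other than themselves. These 16, among them LOC100487455 with the histone symbol h2ax, took 7.11% of FPKM at NF10.5, the stage on which they were picked, 1.84% at NF16 and 1.07% at NF24. Among the other placed genes, LOC100485835 (ubb) and LOC734001 (ptmap12) carry symbols of other families, and for those without a symbol it cannot be told, because the reference holds 28 histone symbols and the table gives no sequence or product. No biological explanation was tested.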
